A study of Mus musculus with 96 samples.

How the data were processed

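The series profiled RNA of 96 single mouse oocytes and embryos of strain C57BL/6J, with total RNA as the molecule per the labels. Per the labels, females were given PMSG and then hCG 46 h later, and were paired with males of the same strain. Embryo collection began 12 h after hCG and went on every 2 h through the first cleavage. Per the labels' protocols, cumulus cells were removed with hyaluronidase in M2 medium, embryos were cultured in KSOM and left untreated, and libraries were made with SMART-Seq v4 and Nextera XT. SMART-Seq v4 primes cDNA on poly(A) tails, and it does not mark the strand of a transcript. The labels state that embryos from 0 h to the late 2-cell stage (36 h) were processed as 1 cohort, whereas oocytes and morulae went through separate batches. Batch and stage therefore cannot be told apart in the comparison of 0 h embryos with oocytes and in that of morulae with 36 h embryos.

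The deposited table holds expected counts for 55401 genes, given by Ensembl identifier with version, and for 873 repeat families. The values are not normalised: 28.4% of the non-zero gene values and 70.6% of the non-zero repeat values are not whole numbers, mostly multiples of simple fractions, and totals differ between libraries. Per the submitters' processing notes, reads were processed with Trimmomatic 0.39, STAR and featureCounts on mm10. The notes give neither the release of the annotation, the repeat annotation, the use of strand nor the options that made the fractions. Reads were thus shared between places or features, and genes of near-identical families, overlapping genes and antisense genes are uncertain. The comparisons planned before the data were examined assumed whole counts. The expected counts were rounded for the count models, and the planned tests were kept. Symbols and coordinates come from GENCODE M21 (GRCm38, the assembly of mm10): 55141 identifiers matched without the version, 54349 with it, and 260 had no symbol. Where several identifiers shared a symbol, the symbol stayed with the one with most counts.

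Gene counts per library ranged from 10378 (morula replicate 4) to 6795311, with a median of 2099222. The second lowest total was 564538. Counts were put on the CPM scale, computed from the rounded gene counts, with library sizes scaled by TMM factors estimated once over all 96 libraries and repeat families left out of the total. Repeat families were put on the same scale, as CPM of the scaled gene counts. A count of 0 was given a floor of 3 counts over the group. Folds against a group at 0 were computed against that floor, and for a group with 1 to 3 counts the ratio of pooled counts is given with its exact conditional 95% interval. Shares of counts in single libraries carry a 95% Wilson interval. Amplified reads without molecular identifiers are not independent molecules, so intervals and floors cover counting error only.

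Samples were grouped by the stage and hour in the labels: 16 groups of 2 to 10 libraries. The groups, tests, alternatives, gene lists and the rule for named genes were fixed before the data were examined. The 5 main comparisons were 0 h with oocytes, 12 h with 0 h, 24 h with 12 h, 36 h with 24 h, and morulae with 36 h. A further 12 comparisons covered the consecutive 2-hour intervals from 0 h to 24 h. Each used only the libraries of its pair of groups in edgeR 4.0.16 (R 4.3.3): filterByExpr, TMM scaling, a trended dispersion, and the robust quasi-likelihood F test, two-sided, with Benjamini-Hochberg adjustment over the genes tested and a threshold of 0.05. Every adjusted p for a gene or a repeat family is from that test unless another tool is named. Fold changes are on the log2 scale with their standard error (SE), and levels are means ± SD over libraries.

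Onset was timed in 1 edgeR fit of the 81 libraries of 0 h to 36 h, in which every later time was tested against 0 h. Genes higher at 36 h by at least 2-fold were given the earliest time from which they were past the test, and at least 2-fold higher, at that and every later time. In the self-test on 18543 simulated genes, 100 rose 4-fold at 16 h and 100 at 24 h. Of these 49 and 38 were called at 36 h, and 26 and 29 given their time. The pairwise test recovered 95.0% of genes changed 4-fold and 72.0% of those changed 2-fold for 0 h with oocytes (9556 genes tested). The respective shares were 91.0% and 35.0% for 12 h with 0 h (8211 genes), 77.0% and 9.0% for 24 h with 12 h (11083 genes), 67.0% and 6.0% for 36 h with 24 h (12636 genes), and 73.0% and 11.0% for morulae with 36 h (11216 genes).

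Gene lists were 29 sets of symbols fixed in advance: zona and secreted proteins, maternal-effect genes, meiotic maturation, mRNA decay and poly(A) control, the 2-cell program, the Obox family, activation regulators, ribosomal proteins, ribosome biogenesis, splicing, RNA polymerase II, translation factors, the proteasome, nuclear-encoded respiratory chain, mitochondrial genome, glycolysis, DNA replication, DNA methylation, histone modifiers, replication-dependent histones, heat shock and stress, pluripotency, trophectoderm, polarity and junctions, primitive endoderm, cumulus and granulosa cells, sperm, blood and oviduct, and Y-linked genes. The last 4 mark other cells, or transcripts that no oocyte can hold. Each list with at least 3 genes tested was compared with all other genes by camera of limma 3.58.1 on log2 CPM (prior count 2) with a preset correlation of 0.01, and again with an estimated correlation. Adjustment was over the lists of a comparison, and members were also counted after adjusting the gene tests over the list alone. With an estimated correlation no list of any of the 5 main comparisons passed the threshold.

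Named genes were chosen by rule. In a main comparison they were the 10 largest log2 changes in each direction among genes past the test, at least 2-fold changed, with a mean of at least 50 CPM in the higher group and no overlap between the groups. Names that are only clone or model numbers were passed over. Steps of 2 h gave the 3 largest in each direction by the same rule. Each list gave up to 4 members past the test with the largest change and at least 10 CPM in the higher group. The comparison of repeat families was added after the deposited table was seen, and the 9 families named were chosen after their values were seen. Repeat families were tested as genes were, scaled to the gene libraries, and their share of all counts was compared with an exact two-sided permutation test in 15 comparisons, adjusted by Benjamini-Hochberg.

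The alternatives were DESeq2 size factors, library size without TMM, the DESeq2 1.42.0 Wald test, no filter on low counts, a 2-fold limit, 1 fit of all 81 cohort libraries (all 96 where oocytes or morulae took part), only titles with or without the suffix b, the 4 h and 6 h libraries as 1 group, the title number as a replicate block, and each library left out in turn (the 0 h libraries for onset). Some alternatives were added after the data were seen: fits without 10 h replicate 5, the estimated correlation without morula replicate 4, the repeat share at 36 h and 24 h without suffix b, the tally of onset genes by their change at 0 h, and the checks of genes that moved in opposite directions around 0 h. Morula replicate 4 was kept in every main fit, and its fold changes rest on few counts. Other calculations used Python 3.11.15 with numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3, and plots were drawn with matplotlib 3.10.9. The labels do not tie embryos to dams, so every p-value measures the spread between embryos and not between litters. The raw reads were not used here.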

Results

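Expected counts for genes and repeat families were collected from 96 single oocytes and embryos of mouse strain C57BL/6J. The groups were oocytes (n = 8), embryos of 0 h (n = 5), 2 h (n = 5), 4 h (n = 2), 6 h (n = 3), 8 h (n = 5), 10 h (n = 5), 12 h (n = 5), 14 h (n = 5), 16 h (n = 8), 18 h (n = 9), 20 h (n = 5), 22 h (n = 10), 24 h (n = 6) and 36 h (n = 8) after fertilization, and morulae (n = 7). Total gene counts ranged from 10378 in morula replicate 4 and 564538 in an oocyte to 6795311 in a 24 h embryo, with a median of 2099222. The series was designed to follow the transcriptome at short intervals from fertilization through activation of the embryonic genome. Titles of the 4 h and 6 h libraries share a numbering series, so these hours are less certain than the others. Some titles from 16 h to 24 h end in the letter b, and its meaning is not stated.

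A pair of libraries stood apart and stayed in the comparisons of their groups. Replicate 5 of 10 h had a median correlation of 0.159 with the other 10 h embryos, and morula replicate 4 had one of 0.431 with the other morulae. Transcripts of cumulus and granulosa cells, summed over the fixed list, reached 3201 CPM in 10 h replicate 5, against a median of 107.5 CPM over the other 95 libraries. Group medians of the list were 379 CPM in oocytes, 150.02 CPM at 0 h, 377 CPM at 8 h, 190.9 CPM at 10 h, 239.6 CPM at 12 h, 223 CPM at 14 h, 80.01 CPM at 16 h, 56.4 CPM at 24 h, 40.5 CPM at 36 h and 2.01 CPM in morulae. Single libraries stood higher, with 791 CPM in 0 h replicate 5, 1477 CPM in 8 h replicate 2, 452 CPM in 36 h replicate 3 and 36.9 CPM in morula replicate 4. The blood and oviduct list had a median of 66.4 CPM in oocytes, 40.9 CPM at 0 h, 30.05 CPM at 16 h and 434 CPM at 22 h, with 2316 CPM in 0 h replicate 1, 2033 CPM in 16 h replicate 4 and 5704 CPM in 22 h replicate 4. Y-linked genes were above the floor of 3 counts in 0 of 8 oocytes, in 0 embryos at 0 h, 2 h, 4 h, 6 h, 12 h and 14 h, in 1 of 5 at 8 h and at 10 h, in 7 of 8 at 16 h, 2 of 9 at 18 h, 1 of 5 at 20 h, 7 of 10 at 22 h, 5 of 6 at 24 h and 6 of 8 at 36 h, and in 3 of 7 morulae. No Y-linked gene passed the filter on low counts in a main comparison.

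The comparison of 0 h embryos with oocytes asked what differed around fertilization, across a difference in processing batch. CPM values of most egg-coat and secreted-protein genes tested were higher at 0 h. So were those of Khdc3, Tle6 and Nlrp5, of the subcortical maternal complex, and of many respiratory-chain subunits. Those of the mitochondrial genome were lower at 0 h. Poly(A)-primed libraries cannot separate message abundance from poly(A) tail length, so either could underlie these differences. Steroid enzyme genes Cyp11a1 and Akr1c18 were lower at 0 h, as was the cumulus list median, so cumulus RNA is not excluded. Of 9556 genes tested, 2224 were higher and 2147 lower at 0 h by edgeR's quasi-likelihood test, 4371 in total, and 1 fit of all 96 libraries called 1601. The groups did not overlap for 1162 genes higher and 941 lower at 0 h, where chance gives 0.155% of genes.

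Among single genes, Idua (ENSMUSG00000033540.18; chromosome 5, 108660331 to 108684557), which encodes a lysosomal iduronidase, rose most, from 1.76 ± 0.895 CPM (SD, n = 8) to 176 ± 27.7 CPM (SD, n = 5), a log2 change of 6.63 ± 0.22 (SE; adjusted p = 4.5e-17). Khdc3 (ENSMUSG00000092622.8; chromosome 9, 73101836 to 73104438), a member of the subcortical maternal complex, rose from 4.12 ± 2.35 to 223 ± 52.4 CPM (log2 change 5.87 ± 0.25, adjusted p = 1.2e-14). Other genes higher at 0 h were Dpys, a pyrimidine-degrading enzyme (2.04 to 120 CPM, log2 change 5.96), the elongin B-like gene Elobl (90.97 to 3289 CPM, 5.20) and Lsm4, a component of U6 snRNA particles (2.63 to 95.1 CPM, 5.03). Tm2d1, which encodes a membrane protein, changed by 4.92 on the log2 scale, and Ndufa5, a complex I subunit, by 4.76. The ubiquitin-conjugating enzyme Ube2t rose from 61.6 to 1467 CPM (log2 change 4.62), the pluripotency-associated Dppa5a from 14.01 to 293 CPM (4.49), and Tmem29 from 4.12 to 91.7 CPM (4.37).

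Cyp11a1, the side-chain cleavage enzyme of steroid synthesis, was lower at 0 h, with 0.538 ± 0.535 CPM from 4 counts against 178 ± 127.1 CPM in oocytes (log2 change -8.12 ± 1.58, adjusted p = 0.00132). Akr1c18 had 2 counts at 0 h and a pooled ratio of 223 in favour of oocytes (95% counting interval 61.5 to 1843). It fell under the filter without oocyte replicate 1, 2, 4, 5 or 6. The mitochondrial RNA-binding protein gene Fastkd2 fell from 55.3 to 7.92 CPM (log2 change -2.81), the zinc-finger gene Zfp932 from 82.7 to 12.2 CPM (-2.74), and Snrnp70, the U1 snRNP 70-kDa protein, from 94.9 to 14.02 CPM (-2.74). Also lower at 0 h were the PDZ protein gene Tax1bp3 (-2.32), the transporter gene Slc35a4 (-2.31), the lipoprotein receptor Scarb1 (-2.27), the cochaperone Stip1 (-2.20) and the secreted angiopoietin-like Angptl2 (-2.18).

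Zona and secreted-protein genes were higher at 0 h in 7 of 10 tested and lower in 0, with 7 and 0 adjusted over the list alone. Camera gave an adjusted p of 0.000460 with the preset correlation and an adjusted p = 0.325 with an estimated correlation. Zp2, a zona pellucida protein, rose from 90.9 to 1020.1 ± 685 CPM, Zp3 from 71.1 to 564 ± 146 CPM, the oocyte growth factor Bmp15 from 673 to 3187 ± 528 CPM, and the cortical granule protease Astl from 60.8 to 253 ± 23.2 CPM. In the nuclear-encoded respiratory chain 38 of 69 genes were higher and 7 lower (39 and 10 adjusted over the list alone; camera adjusted p = 3.0e-06, and adjusted p = 0.379 with an estimated correlation), among them Uqcr11 (10.6 to 171 CPM), Ndufa1 (20.9 to 231 CPM) and Cox6a1 (23.97 to 234 CPM). All 12 genes tested of the mitochondrial genome were lower at 0 h (12 adjusted over the list alone; camera adjusted p = 6.8e-07, and adjusted p = 0.325 with an estimated correlation), for example mt-Nd3 (195 to 47.7 CPM) and mt-Nd4l (225 to 59.9 CPM).

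Meiotic-maturation genes were higher in 11 and lower in 4 of 22 (13 and 5 adjusted over the list alone; camera adjusted p = 0.0426, and adjusted p = 0.325 with an estimated correlation), with the meiotic kinase Mos rising from 113.5 to 922 ± 86.4 CPM and the survivin gene Birc5 from 159.6 to 1119 ± 334 CPM. Only 3 of 71 replication-dependent histone genes on the list were tested. All 3 were higher (3 adjusted over the list alone, camera adjusted p = 0.0419, and adjusted p = 0.371 with an estimated correlation), and Hist1h2bc rose from 19.4 to 246 ± 97.9 CPM. Among maternal-effect genes 11 of 23 were higher and 6 lower (12 and 6 adjusted over the list alone; camera adjusted p = 0.166). Tle6 and Nlrp5, both of the subcortical maternal complex, rose from 70.5 to 590.5 CPM and from 246 to 1361 CPM. Of the activation regulators 1 of 13 was higher and 7 lower (1 and 7 adjusted over the list alone), with the NF-Y subunit gene Nfyc falling from 132.9 to 36.03 CPM and Klf17 from 1032 to 428 CPM. The 2-cell program had 2 higher and 1 lower of 7 (2 and 1 adjusted over the list alone). Its median change was -0.13, its mean 0.57. Of the cumulus list 1 gene was higher and 1 lower of 7 (the same adjusted over the list alone; median log2 change 0.94, mean -0.22; camera adjusted p = 0.748). The number of lists called with the preset correlation was 5, and 3 without oocyte replicate 2 or 0 h replicate 4.

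The first 12 hours within the embryo cohort were examined by comparing 12 h with 0 h. Many of the genes that were higher at 0 h than in oocytes fell by 12 h, including Idua, Khdc3 and Elobl. Abundance and poly(A) tail length cannot be told apart here either. The replication gene Cdc45 and the translation-initiation gene Eif2s1 rose, as did the zinc-finger genes Zfp932, Zfp735, Zfp943 and Zfp982. As lists, transcripts of the mitochondrial genome lay above other genes and those of nuclear respiratory-chain subunits and ribosomal proteins below, with the preset correlation only. Of 8211 genes tested, 1616 were higher and 1590 lower at 12 h, 3206 in total, and 1 fit of the 81 libraries of 0 h to 36 h called 1620. Scaling by library size alone moved the median log2 change of all genes from -0.02 to -0.29 and the split to 1005 higher and 2240 lower. The groups did not overlap for 1030 genes higher and 1120 lower, where chance gives 0.794% of genes.

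Fastkd2 rose from 7.92 ± 7.14 CPM (SD, n = 5) to 79.5 ± 19.9 CPM (SD, n = 5), a log2 change of 3.34 ± 0.50 (SE; adjusted p = 7.9e-05). Cdc45 (ENSMUSG00000000028.15; chromosome 16, 18780447 to 18811987), a part of the replicative helicase, rose from 42.4 ± 7.22 to 241 ± 64.6 CPM (log2 change 2.51 ± 0.21, adjusted p = 2.1e-07). The COP9 signalosome gene Cops2 rose from 78.6 to 464 CPM (log2 change 2.55), the eIF2 alpha gene Eif2s1 from 40.1 to 216 CPM (2.43), and the thioesterase gene Lypla1 from 63.4 to 331 CPM (2.38). Zinc-finger genes that rose were Zfp932 (3.02), Zfp735 (167 to 942 CPM, 2.49), Zfp943 (2.46) and Zfp982 (2.45). Idh1, an isocitrate dehydrogenase, averaged 270.5 ± 333 CPM at 12 h (log2 change 2.85, adjusted p = 0.0180). Its call was lost without the filter on low counts and under DESeq2.

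Genes that fell were led by Idua, down to 3.72 ± 2.65 CPM (log2 change -5.72 ± 0.40, adjusted p = 1.6e-08), and Khdc3, down to 6.24 ± 1.499 CPM (log2 change -5.17 ± 0.27, adjusted p = 6.9e-10). Ndufa5 changed by -4.84, Lsm4 by -4.75, Tm2d1 by -4.07 and Elobl by -4.59 on the log2 scale, with Elobl at 132.2 ± 172 CPM at 12 h. Mis18a, which helps load the centromeric histone, fell from 297 to 14.2 CPM (-4.35) and the calmodulin gene Calm2 from 553 to 31.3 CPM (-4.08). Hist1h2bc fell from 246 to 13.0 CPM (-4.21) and the beta-tubulin gene Tubb2b from 63.7 to 3.76 CPM (-4.19). Reads of histone and tubulin genes can be shared with near-identical copies, so these values are uncertain.

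Nuclear respiratory-chain genes were lower in 34 and higher in 5 of 60 (35 and 5 adjusted over the list alone; camera adjusted p = 1.3e-06, and adjusted p = 0.692 with an estimated correlation), with Uqcr11 falling from 171 to 11.4 CPM and Cox6a1 from 234 to 18.9 CPM. Ribosomal protein genes were lower in 17 and higher in 0 of 37 (17 lower adjusted over the list alone; camera adjusted p = 3.5e-05, and adjusted p = 0.692 with an estimated correlation), with Rplp1 falling from 107.2 to 8.78 CPM. The mitochondrial genome had 8 of 11 genes higher (9 adjusted over the list alone; camera adjusted p = 0.00175, and adjusted p = 0.692 with an estimated correlation), with mt-Cytb rising from 2081 to 6075 CPM and mt-Nd5 from 350.1 to 1011 CPM. Of the DNA methylation genes 6 of 10 were lower (7 adjusted over the list alone; camera adjusted p = 0.0229, and adjusted p = 0.356 with an estimated correlation), with the maintenance methyltransferase Dnmt1 falling from 1202 to 183 CPM and Dnmt3l from 90.7 to 16.6 CPM. Zona and secreted-protein genes were lower in 7 of 10 (7 adjusted over the list alone; camera adjusted p = 0.0198, and adjusted p = 0.356 with an estimated correlation), Zp3 among them (564 to 131.5 CPM). The 3 replication-dependent histone genes tested were lower (camera adjusted p = 0.0198, and adjusted p = 0.356 with an estimated correlation).

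Lists without a camera call also held genes past the test. DNA replication genes were higher in 12 and lower in 2 of 29 (12 and 2 adjusted over the list alone), with the origin gene Orc3 rising from 7.66 to 22.5 CPM. Histone modifiers were lower in 9 and higher in 1 of 25 (9 and 1 adjusted over the list alone), with the acetyltransferase gene Crebbp falling from 222 to 68.7 CPM and the demethylase gene Kdm6b from 77.3 to 21.2 CPM. The 4 Obox genes tested were higher (4 adjusted over the list alone; camera adjusted p = 0.112), such as Obox1 (5514 to 9733 CPM), although near-identical Obox copies share reads. Polarity and junction genes were lower in 6 and higher in 2 of 14 (6 and 2 adjusted over the list alone). The basement-membrane gene Lamb1, of the primitive endoderm list, fell from 606 to 126.8 CPM. Of the cumulus list 1 gene of 6 was higher, Cyp19a1 (70.7 to 138.7 CPM), a call lost with library size alone and without 12 h replicate 4 or 0 h replicate 1. The oviduct gene Ovgp1 fell from 24.7 to 1.71 CPM.

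Across genes, the changes of these comparisons mirrored one another around 0 h. Of 8192 genes tested in both, 1291 were higher at 0 h than in oocytes and then lower at 12 h, where independent lists of these sizes would share 417, and 1086 went the opposite way, where independent lists would share 361. Another 22 genes changed in the same direction in both. The correlation of the log2 changes across genes, which are not independent replicates, was -0.844 with a covariance of -0.869. Unchanged groups simulated against shared 0 h libraries gave correlations from -0.569 to -0.552, covariances from -0.0579 to -0.0533 and 0 genes called in edgeR's test in 5 simulations. Khdc3, Idua, Elobl, Lsm4 and Ndufa5 were among the genes named in both comparisons. Average correlation with the mean oocyte was 0.853 at 0 h, 0.892 at 2 h, 0.907 at 4 h, 0.921 at 12 h, 0.940 at 14 h and 0.645 at 36 h.

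**Figure D1:**
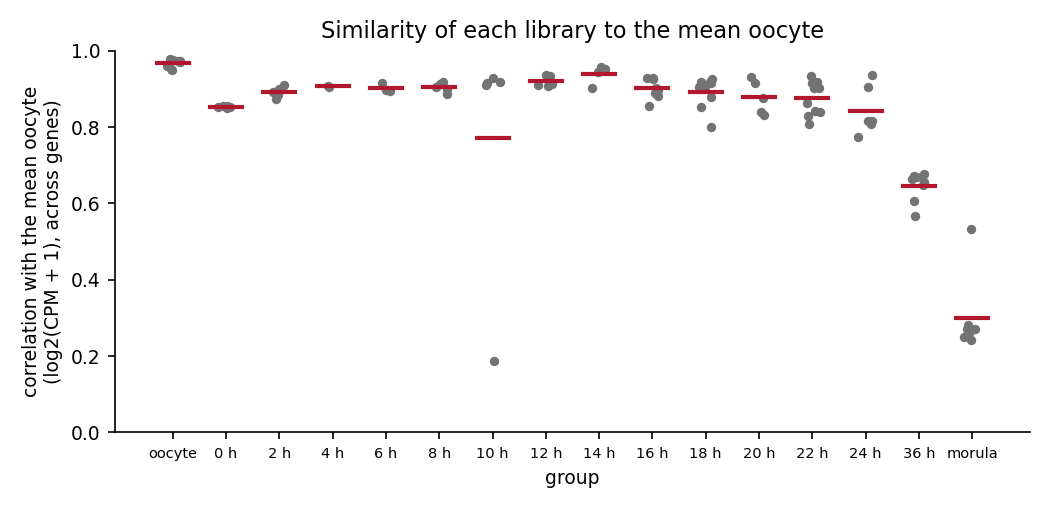
Correlation across genes of each library with the mean oocyte profile (y axis, no unit) for each group (x axis, stage or hours after fertilization), with grey dots for libraries and red bars for group means. The mean is 0.853 at 0 h, 0.940 at 14 h and 0.301 in morulae, and 10 h replicate 5 lies far below its group.

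The passage from 1 cell to 2 cells was examined by comparing 24 h with 12 h. In the 2-cell program 5 of 10 genes tested rose, without a call of the list, as did the double-homeobox gene Duxbl1, and transcripts of the meiotic kinase Mos, the oocyte linker histone H1foo and the growth factor Gdf9 fell. As lists, ribosomal protein and mitochondrial-genome transcripts lay above other genes with the preset correlation only. The 24 h embryos differed widely in 2-cell transcripts. Of 11083 genes tested, 1485 were higher and 912 lower at 24 h. Scaling by library size alone moved the median log2 change of all genes from 0.05 to 0.25 and the split to 1832 higher and 600 lower. The groups did not overlap for 759 genes higher and 444 lower, where chance gives 0.433% of genes. Without embryos whose titles end in b the count of genes called rose from 2397 to 4068.

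Zscan4d, a zinc-finger gene of the 2-cell program, averaged 161 ± 243 CPM (SD, n = 6) at 24 h and 1.77 ± 1.12 CPM (SD, n = 5) at 12 h, a log2 change of 6.35 ± 1.65 (SE; adjusted p = 0.0146). Its call was lost without the filter on low counts and without 12 h replicate 1, 2, 3 or 4 (highest adjusted p 0.0595), and it fell under the filter without 24 h replicate 1, 3, 4 or 5. Reads of near-identical Zscan4 copies are shared, so its level is uncertain. Duxbl1 (ENSMUSG00000048502.14; chromosome 14, 25978577 to 25990088), a double-homeobox gene, rose from 3.53 ± 2.59 to 83.7 ± 53.4 CPM (log2 change 4.68 ± 0.68, adjusted p = 0.000805). Ube2a, a ubiquitin-conjugating enzyme of DNA repair, rose from 8.96 to 167 CPM (log2 change 4.26), and the apoptosis inhibitor Aven from 14.8 to 221 CPM (3.94). Also higher were the uridine kinase Uck2 (4.04), the lysophospholipid transporter Mfsd2a (3.93), the immunoglobulin-superfamily gene Cd7 (3.85), the oligoadenylate synthetase gene Oas1f (3.61), the small GTPase gene Rab3b (3.61) and the carbonic anhydrase Car9 (3.59).

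Sumo2 (ENSMUSG00000020738.16; chromosome 11, 115523102 to 115536276), which encodes a ubiquitin-like modifier, fell from 323 ± 117.5 to 22.6 ± 17.5 CPM (log2 change -3.83 ± 0.48, adjusted p = 0.000452). Mos fell from 117.2 ± 91.5 to 10.4 ± 4.54 CPM (log2 change -3.51 ± 0.52, adjusted p = 0.000852), and H1foo from 6112 ± 2136 to 707.4 ± 652 CPM (log2 change -3.10 ± 0.51, adjusted p = 0.00143). The protease inhibitor Serpini1 changed by -3.56 on the log2 scale and the cohesin gene Smc3 by -3.36, a call lost without the filter on low counts. Tmem59 changed by -3.19, the calcium-entry regulator Saraf by -3.11, the disulfide isomerase P4hb by -3.02 and the coatomer gene Arcn1 by -2.99. Gdf9, an oocyte growth factor of the zona and secreted list, fell from 4185 to 558 CPM.

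Of 55 ribosomal protein genes 3 were higher and 0 lower, with 0 adjusted over the list alone (camera adjusted p = 0.00529, and adjusted p = 0.882 with an estimated correlation), Rps24 among them (7.93 to 22.2 CPM). The mitochondrial genome had 3 of 13 higher (6 adjusted over the list alone; camera adjusted p = 0.0396, and adjusted p = 0.882 with an estimated correlation), such as mt-Co2 (2.87 to 11.3 CPM). Replication-dependent histone genes had 5 of 9 higher (6 higher and 1 lower adjusted over the list alone; camera adjusted p = 0.0183, and adjusted p = 0.549 with an estimated correlation). These 3 list calls became 6 without 12 h replicate 3, 5 without 12 h replicate 4, 1 without 24 h replicate 3 or 4, and 0 without 24 h replicate 1. The 2-cell program had 5 higher of 10 (6 adjusted over the list alone; camera adjusted p = 0.145). In mRNA decay and poly(A) control 4 of 26 were higher and 3 lower (the same numbers adjusted over the list alone; median log2 change -0.06, mean 0.28, placed below other genes by camera), with the cap-binding gene Eif4e1b rising from 33.7 to 167 CPM and the deadenylase gene Parn from 6.51 to 31.1 CPM. Among stress genes 3 were higher and 4 lower of 12 (4 and 4 adjusted over the list alone), with the transcription factor Atf4 rising from 21.97 to 98.3 CPM. Among translation factors 8 were higher and 2 lower of 33 (9 and 2 adjusted over the list alone; median log2 change -0.06, mean 0.24), with Eif1ax rising from 20.5 to 126.8 CPM.

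The late 2-cell stage was examined by comparing 36 h with 24 h, where genome activation is known to peak. Ribosomal protein genes rose nearly as a whole, and transcripts of maternal-effect and zona genes fell nearly as a whole. Zfp42, Klf4 and Klf5, regulators of pluripotent cells, rose along with metallothionein Mt1. The histone mRNA-binding gene Slbp and the oocyte-expressed Nlrp4f and Oog4 fell. Of 12636 genes tested, 3671 were higher and 2936 lower at 36 h. Scaling by library size alone moved the median log2 change of all genes from 0.05 to 0.29 and the split to 4172 higher and 2232 lower, and DESeq2 size factors moved the median to 0.16. The groups did not overlap for 1335 genes higher and 1440 lower, where chance gives 0.0666% of genes.

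Ctsz, which encodes the lysosomal protease cathepsin Z, rose from 0.753 ± 0.278 CPM (SD, n = 6) to 69.7 ± 28.5 CPM (SD, n = 8), a log2 change of 6.50 ± 0.41 (SE; adjusted p = 2.1e-08). Mt1 (ENSMUSG00000031765.8; chromosome 8, 94179082 to 94180327) rose from 20.4 ± 23.7 to 649.6 ± 233 CPM (log2 change 5.03 ± 0.63, adjusted p = 1.7e-05), and Zfp42, also known as Rex1, from 1.65 ± 2.18 to 81.7 ± 56.6 CPM (log2 change 5.50 ± 0.73, adjusted p = 2.3e-05). The selenoprotein gene Selenos rose from 5.51 to 205 CPM (log2 change 5.21), the vitamin B6 kinase Pdxk by 5.38, the ribonuclease P gene Rpp40 by 5.13, the cyclin-like Ccnjl by 5.08 and the cell-cycle regulator Rgcc by 4.91. The unclassified transcript AA414992 rose by 5.94 and the antisense transcript AC132367.1 by 6.30. The use of strand is not stated, so reads of AC132367.1 cannot be separated from those of its overlapping partner.

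Slbp (ENSMUSG00000004642.13; chromosome 5, 33634952 to 33652574) fell from 5513 ± 1659 to 239 ± 49.6 CPM (log2 change -4.44 ± 0.24, adjusted p = 6.1e-09). Rgs2, a regulator of G-protein signalling, fell from 2044 ± 1406 to 69.9 ± 33.3 CPM (log2 change -4.78 ± 0.50, adjusted p = 2.5e-06). Slf1, which localises the SMC5/6 complex, changed by -4.84 on the log2 scale, the interferon-induced family member Ifit1bl2 by -4.43, Fam90a1a by -4.13, the chemerin-binding receptor Gpr1 by -3.97 and the olfactory receptor gene Olfr976 by -3.92. The homeobox gene Obox2 fell from 7944 ± 8156 to 440.1 ± 186 CPM (-4.08), Oog4 from 1735 to 98.7 CPM (-4.03) and Nlrp4f from 1825 to 106.6 CPM (-3.98). Near-identical copies of Obox, Oog and Nlrp4 genes share reads, so these levels are uncertain.

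Of 84 ribosomal protein genes 72 were higher and 2 lower (75 and 3 adjusted over the list alone; camera adjusted p = 6.2e-15, and adjusted p = 0.266 with an estimated correlation), such as Rpsa (2.22 to 28.2 CPM) and Rps29 (1.40 to 23.3 CPM). Maternal-effect genes were lower in 21 and higher in 0 of 23 (21 adjusted over the list alone; camera adjusted p = 1.3e-10, and adjusted p = 0.0603 with an estimated correlation), with the NLR-family genes Nlrp4b, Nlrp9b and Nlrp4a falling from 615 to 43.1, from 524 to 37.3 and from 1187 to 85.1 CPM. All 11 zona and secreted-protein genes were lower (11 adjusted over the list alone; camera adjusted p = 0.000807, and adjusted p = 0.266 with an estimated correlation), with Oosp2 falling from 181 to 31.5 CPM. Meiotic-maturation genes were lower in 11 and higher in 1 of 22 (the same numbers adjusted over the list alone; camera adjusted p = 0.00180, and adjusted p = 0.266 with an estimated correlation), with the securin Pttg1 falling from 6456 to 913 CPM. In mRNA decay and poly(A) control 15 were lower and 4 higher of 28 (the same numbers adjusted over the list alone; camera adjusted p = 0.0166, and adjusted p = 0.266 with an estimated correlation). The oocyte poly(A)-binding Pabpn1l fell from 107.8 to 11.4 CPM while Pabpc1 rose from 3.76 to 46.8 CPM.

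The mitochondrial genome had all 13 genes higher (13 adjusted over the list alone; camera adjusted p = 0.000373, and adjusted p = 0.517 with an estimated correlation), with mt-Cytb rising from 8628 ± 4101 to 32102 ± 13664 CPM. The nuclear respiratory chain had 34 higher and 9 lower of 73 (the same numbers adjusted over the list alone; camera adjusted p = 0.00180, and adjusted p = 0.337 with an estimated correlation), such as Ndufs8 (4.93 to 51.6 CPM). RNA polymerase II genes were higher in 9 of 12 (9 adjusted over the list alone; camera adjusted p = 0.0256, and adjusted p = 0.266 with an estimated correlation), such as Polr2l (12.6 to 55.8 CPM). The 2-cell program was called as higher (camera adjusted p = 0.000807, and adjusted p = 0.649 with an estimated correlation) with 5 higher and 2 lower of 33 (5 and 1 adjusted over the list alone). Its genes Tdpoz1 and Usp17lb rose from 6.97 to 105.2 CPM and from 27.0 to 265 CPM, and E330021D16Rik fell from 6322 to 259 CPM. Ribosome biogenesis genes were higher in 21 and lower in 4 of 45 (the same numbers adjusted over the list alone; camera adjusted p = 0.0504), with Nop16 rising from 5.30 to 118.3 CPM. Activation regulators were higher in 7 and lower in 4 of 18 (7 and 5 adjusted over the list alone; median log2 change -0.04, mean 0.77), with Klf5 rising from 2.42 to 43.9 CPM, Klf4 from 3.71 to 31.1 CPM and the GA-binding Gabpa from 23.96 to 243 CPM.

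Camera called none of the remaining lists at 36 h, although single members passed the test. Glycolysis genes were higher in 9 and lower in 1 of 15 (the same numbers adjusted over the list alone; camera adjusted p = 0.0920), with Ldha rising from 4.54 to 66.7 CPM and Ldhb falling from 2825 to 557 CPM. DNA methylation genes went both ways (6 higher, 5 lower of 15, the same numbers adjusted over the list alone), with Dnmt1 falling from 184 to 12.7 CPM and Uhrf2 rising from 2.56 to 30.3 CPM. Their median log2 change was 0.25 and their mean -0.08. In the pluripotency list 5 were higher and 2 lower of 10 (5 and 3 adjusted over the list alone), and in the trophectoderm list 6 and 2 of 9 (the same adjusted over the list alone), with Id2, a call lost without the filter on low counts, at 31.9 and 130.2 CPM. Polarity and junction genes were higher in 7 of 21 and lower in 1 (the same adjusted over the list alone), with the junction gene F11r rising from 3.93 to 53.8 CPM. The blood and oviduct list had 1 of 4 higher, the epithelial adhesion gene Epcam (5.10 to 77.8 CPM), and the sperm list 1 of 4, Ldhc (2.71 to 11.2 CPM).

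**Figure D2:**
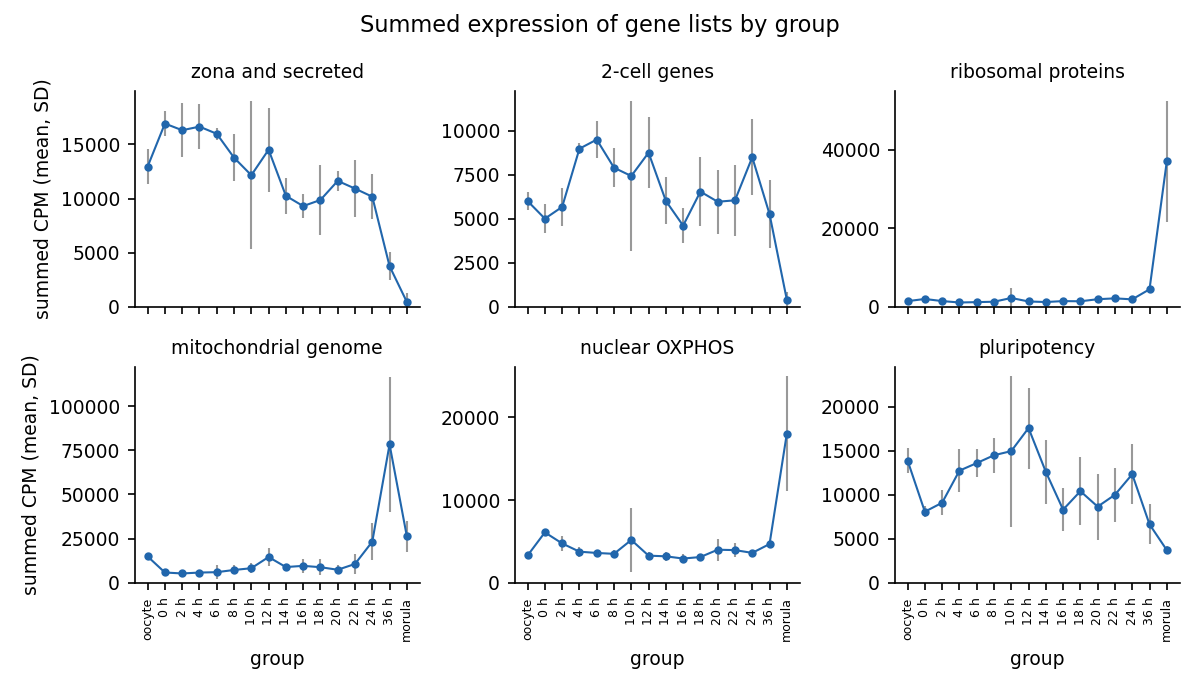
Summed CPM of 6 gene lists (y axes) in each group from oocytes to morulae (x axes), with points for group means and bars for SD over libraries. Mitochondrial-genome transcripts peak at 36 h and ribosomal protein transcripts rise at 36 h and again in morulae.

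Morulae were compared with 36 h embryos across a difference in processing batch. Genes for ribosomal proteins, the respiratory chain, the proteasome and translation factors mostly rose, and most of those of the 2-cell program fell. Timd2, Calcoco2 and Ndufa12 of complex I rose strongly. Of 11216 genes tested, 3162 were higher and 4883 lower in morulae, 8045 in total, and 1 fit of all 96 libraries called 13219. The median log2 change of all genes was -0.55, and it was -0.88 with DESeq2 size factors and -0.78 with library size alone, so changes are relative to that shift. The groups did not overlap for 631 genes higher and 2570 lower, where chance gives 0.0311% of genes. Gene means for morulae leave out replicate 4, which had 10378 counts.

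Vnn1, a pantetheinase, averaged 0.678 ± 1.26 CPM (SD, n = 8) at 36 h and 140.1 ± 36.2 CPM (SD, n = 6) in morulae, and its log2 change in the fit of all libraries was 7.52 ± 0.62 (SE; adjusted p = 3.6e-10). Rpl38 (ENSMUSG00000057322.12; chromosome 11, 114668524 to 114672331), a ribosomal protein, rose from 3.85 ± 2.20 to 227 ± 70.4 CPM (log2 change 5.85 ± 0.40, adjusted p = 4.1e-11). Timd2, a receptor of the TIM family, rose from 143 to 14082 CPM (log2 change 6.60), the autophagy receptor Calcoco2 from 41.8 to 3596 CPM (6.36) and Ndufa12 from 3.85 to 302 CPM (6.25). The nucleotidase gene Nt5c changed by 7.51, the vesicle protein gene Syngr1 by 7.45, the methionine-cycle enzyme Bhmt by 6.68 and the mitochondrial ribosome gene Mrps31 by 5.95. Sycn, a zymogen granule protein gene, had 2 counts at 36 h and a pooled ratio of 1034 (95% counting interval 286 to 8546).

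Several genes were not detected in morulae. BC147527 was at least 725-fold lower and the ubiquitin-ligase-like Rfpl4b at least 742-fold lower, against a floor of 3 counts over the group, from 143 ± 63.2 and 130.7 ± 67.1 CPM at 36 h. Pramef6 was at least 307-fold lower and Ccdc82 at least 309-fold. The meiosis gene Meioc was at least 431-fold lower, but fell under the filter without 36 h replicate 1, 2, 3, 4, 5, 6 or 7. The glutathione transferase Gstm1 was at least 273-fold lower, and fell under the filter without 36 h replicate 2, 3, 4, 5, 6, 7 or 8. Zscan4d had 2 counts in morulae and a pooled ratio of 1793 in favour of 36 h (496 to 14811), and Zscan4a 3 counts and a ratio of 1431 (489 to 6940.2). AF067061 had 1 count and a ratio of 2608 (468 to 1.03e+05), and AA414992 1 count and a ratio of 2231 (400.1 to 88137). Zscan4, Pramef6 and related genes have near-identical copies that share reads, so single members are uncertain.

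Of 88 ribosomal protein genes 86 were higher and 1 lower (the same numbers adjusted over the list alone; camera adjusted p = 5.8e-29, and adjusted p = 0.659 with an estimated correlation), with Rps18 rising from 11.5 to 439 CPM. Of 74 nuclear respiratory-chain genes 68 were higher (68 adjusted over the list alone; camera adjusted p = 5.7e-17, and adjusted p = 0.659 with an estimated correlation), with Ndufb7 rising from 8.98 to 381 CPM. Proteasome genes were higher in 31 and lower in 2 of 39 (32 and 2 adjusted over the list alone; camera adjusted p = 8.3e-10, and adjusted p = 0.659 with an estimated correlation), with Psma6 rising from 64.5 to 1124 CPM and Psme4 falling from 302 to 22.8 CPM. Translation factors were higher in 29 of 34 (31 adjusted over the list alone; camera adjusted p = 2.5e-09, and adjusted p = 0.659 with an estimated correlation), with Eif2s2 rising from 128.1 to 3826 CPM. Splicing genes were higher in 36 and lower in 2 of 51 (the same numbers adjusted over the list alone; camera adjusted p = 1.3e-07, and adjusted p = 0.659 with an estimated correlation), with Lsm5 rising from 5.40 to 140.4 CPM. Ribosome biogenesis genes were higher in 29 and lower in 2 of 46 (the same numbers adjusted over the list alone; camera adjusted p = 3.2e-06, and adjusted p = 0.659 with an estimated correlation), with Npm1 rising from 242 to 2304 CPM.

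The 2-cell program was lower in 29 of 32 genes (29 adjusted over the list alone; camera adjusted p = 3.7e-11, and adjusted p = 0.380 with an estimated correlation). Maternal-effect genes were lower in 21 and higher in 2 of 23 (the same numbers adjusted over the list alone; camera adjusted p = 0.0143, and adjusted p = 0.659 with an estimated correlation), with Khdc3 rising from 4.71 to 264 CPM. Zona and secreted-protein genes were lower in 8 of 9 (8 adjusted over the list alone; camera adjusted p = 0.0480, and adjusted p = 0.659 with an estimated correlation), with Zp2 falling from 65.4 to 2.17 CPM. RNA polymerase II genes were higher in 7 and lower in 1 of 13 (the same adjusted over the list alone; camera adjusted p = 0.0159, and adjusted p = 0.659 with an estimated correlation), with Polr2k rising from 4.05 to 75.7 CPM. The pluripotency list had 7 higher and 1 lower of 12 (the same adjusted over the list alone; camera adjusted p = 0.0349, and adjusted p = 0.659 with an estimated correlation), with Dppa5a rising from 187 to 3244 CPM. Replication-dependent histone genes had 6 higher and 2 lower of 8 (the same adjusted over the list alone; camera adjusted p = 0.0480, and adjusted p = 0.659 with an estimated correlation). With library size alone the calls of zona, maternal-effect, pluripotency and histone genes were lost, and that of zona genes also with DESeq2 size factors.

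The mitochondrial genome had 11 of 13 genes lower (11 adjusted over the list alone; camera adjusted p = 0.145), with mt-Co1 falling from 10642 to 2207 CPM. Glycolysis genes were lower in 10 and higher in 1 of 16 (the same adjusted over the list alone), with Tpi1 falling from 66.2 to 5.22 CPM. Activation regulators were higher in 8 and lower in 4 of 19 (the same adjusted over the list alone), with Dppa2 rising from 39.4 to 586 CPM and the trophectoderm regulator Tead4 from 3.70 to 44.6 CPM. In the primitive endoderm list 1 of 3 was higher, the transcription factor Gata6 (13.3 to 122.7 CPM), with a median log2 change of -0.38 and a mean of 0.68 over the list. The meiotic list had a median log2 change of -0.37 and a mean of -1.19, while camera placed it above the other genes (adjusted p = 0.970). Stress genes were higher in 2 and lower in 7 of 14 (the same adjusted over the list alone), with the chaperone Hspa8 rising from 40.2 to 792 CPM. All 3 blood and oviduct genes tested, Hba-a1, Hba-a2 and Epcam, were lower in morulae, and the sperm-tail gene Odf2 fell from 65.1 to 3.97 CPM.

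Steps of 2 h were compared within the first day. From 0 h to 2 h 726 genes changed, 374 higher and 352 lower, and from 14 h to 16 h 1348 changed, 620 higher and 728 lower. Of these, 241 and 762 changed at least 2-fold. From 2 h to 4 h 25 genes changed, from 18 h to 20 h 1 and from 22 h to 24 h 36. The ranking of steps depended on the model. The fit of 81 libraries called 1 gene (2 h), 273 (16 h) and 966 (24 h), and also 566 (10 h) and 973 (12 h). Without 10 h replicate 5 that fit called 17 (2 h), 908 (16 h), 1525 (24 h), 0 (10 h) and 1 (12 h). With the replicate block 793 (2 h), 69 (16 h) and 0 (24 h) were called. In steps to 6, 8, 10, 12, 14, 18 and 22 h edgeR called 0 genes. DESeq2 called 1, 18, 0, 1, 493, 88 and 8. By chance 0.05 of genes have unadjusted p under 0.05. Such genes were 332 of 8284, 443 of 8295, 335 of 7915, 586 of 8311, 1432 of 8929, 1049 of 10016 and 463 of 12069.

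Between 0 h and 2 h the RNA-binding gene Rbm38 rose from 56.7 ± 11.5 to 192 ± 85.5 CPM (log2 change 1.70 ± 0.26, adjusted p = 0.00255), and the imprinted gene Mest from 115.1 ± 22.2 to 316 ± 95.3 CPM (1.39). Rabif changed by 1.39, Ninj2 by -2.05 and Elobl by -1.70. Zp2 changed by -1.96, a call lost without the filter on low counts and without 2 h replicate 1, 4 or 5 or 0 h replicate 4 (highest adjusted p 0.0869). The count of 726 fell to 459, 432 and 361 without 0 h replicates 1, 2 and 3, and to 416, 460 and 352 without 2 h replicates 1, 4 and 5. Between 2 h and 4 h Mis18a fell from 328 ± 92.7 to 26.6 ± 9.82 CPM (-3.55), Khdc3 from 128.6 to 19.6 CPM (-2.66) and Samd10 from 79.8 to 6.28 CPM (-3.54), and Gpr149, Ccdc6 and Strn rose by 1.21, 1.13 and 1.07. Without 1 of the 4 h replicates that group is a single library, so the spread comes from the other group alone. In such fits each of these calls was lost without 4 h replicate 2, and all but that of Mis18a without 4 h replicate 1, which does not test them. Calls of Gpr149, Ccdc6 and Strn were also lost without 2 h replicate 1, 3 or 4, and that of Samd10 without 2 h replicate 4. The 25 genes became 12, 43, 10 and 5 without 2 h replicates 1 to 4, 82 higher and 31 lower without 2 h replicate 5, and 4 and 1 without 4 h replicates 1 and 2. Steps with 0 calls gained 4 and 3 without 4 h replicates 1 and 2 (6 h with 4 h, again with a single 4 h library), and 4 without 8 h replicate 1 (8 h with 6 h).

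Between 14 h and 16 h the mitochondrial ribosomal RNA mt-Rnr1 rose from 173 ± 26.6 to 813 ± 418 CPM (log2 change 2.20 ± 0.36, adjusted p = 0.00259), Csrnp2 from 12.5 to 51.4 CPM (2.10) and Sap30bp from 14.02 to 53.2 CPM (1.92). P4hb fell from 185 to 40.2 CPM (-2.24). Hsd3b1, a steroid-synthesis enzyme, fell from 80.8 ± 90.8 to 1.13 ± 1.44 CPM (-5.90) and the syndecan Sdc1 from 133.7 to 34.6 CPM (-2.003). Both were also abundant in 10 h replicate 5, at 5898 and 1843 CPM. The count of 1348 fell to 823, 816, 673 and 503 without 14 h replicates 1, 3, 4 and 5, and to 624 without embryos whose titles end in b. Of genes higher at 24 h than at 12 h and tested in both, 315 were also higher at 16 h than at 14 h, where independent lists would share 80.6, and 323 were lower in both, where independent lists would share 62.2.

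In the 14 h with 12 h step 1, 307 and 5 genes were called without 12 h replicate 4, 12 h replicate 5 and 14 h replicate 2. In the 18 h with 16 h step 39 and 16 were called without 16 h replicate 3 and 18 h replicate 3, and 2 higher and 28 lower without 18 h replicate 9, and in the 22 h with 20 h step 1 without 22 h replicate 1. Snrnp70 fell between 18 h and 20 h from 129.8 ± 61.7 to 25.2 ± 8.14 CPM (log2 change -2.32 ± 0.37, adjusted p = 0.0375), and its call was lost without any of 18 h replicates 5 to 9 or 20 h replicates 1, 2, 4 and 5. Zfp982 rose (142 to 344 CPM, 1.30) and the splicing-associated Frg1 fell (93.02 to 37.4 CPM, -1.30) between 22 h and 24 h. Both of these calls were lost without embryos whose titles end in b, without 24 h replicate 1 or 4 and without any of 22 h replicates 3 to 10, and that of Frg1 also without 24 h replicate 2 or 3 or 22 h replicate 2. The 36 genes of this step became 39 higher and 51 lower without 22 h replicate 1, 21 without 22 h replicate 2, 0 without any of 22 h replicates 3 to 10 or 24 h replicate 1 or 4, 305 without 24 h replicate 5 and 64 without 24 h replicate 6.

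**Figure D3:**
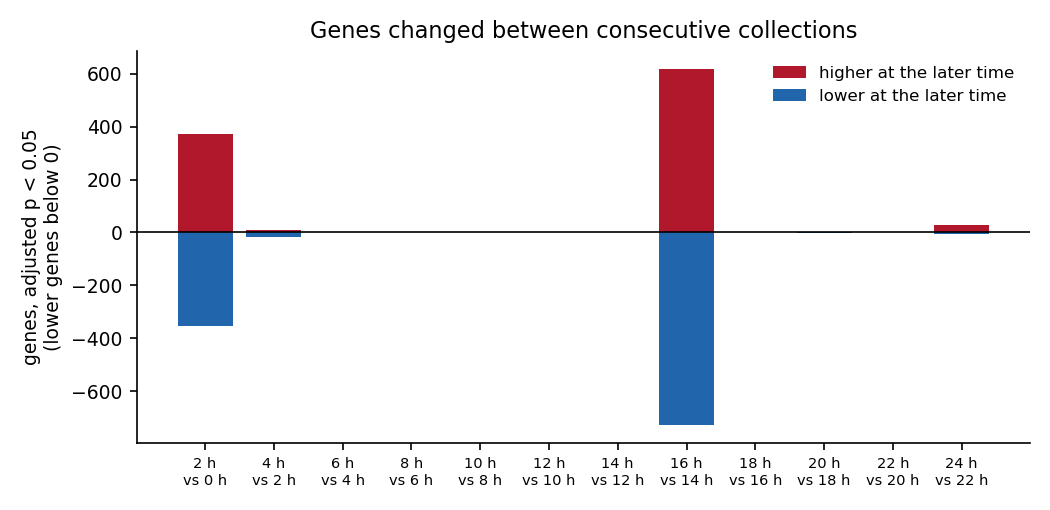
Genes called by edgeR in each 2-hour step (x axis, hours compared), with red bars for genes higher at the later hour and blue bars below 0 for genes lower (y axis, number of genes). The steps to 2 h (726 genes) and to 16 h (1348 genes) hold most of the calls in these pairwise fits, whereas the fit of 81 libraries gave them 1 and 273.

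Times of onset were assigned to 5896 genes higher at 36 h than at 0 h, of 18543 tested in the fit of 81 libraries. By 16 h 380 (6.45%) had their onset, 256 at 16 h itself. A further 860 (14.6%) were timed at 24 h and 4386 (74.4%) at 36 h, but the rule can time rises late. Counts at the other hours were 0 at 2 h, 2 at 4 h, 15 at 6 h, 15 at 8 h, 22 at 10 h, 49 at 12 h, 21 at 14 h, 49 at 18 h, 45 at 20 h and 176 at 22 h. Without 10 h replicate 5 the counts at 2 h, 4 h, 6 h, 8 h, 14 h and 20 h were 4, 11, 30, 24, 38 and 68, each moved more than 1.5-fold. Of genes with onset from 2 h to 14 h all 96 that were tested at 0 h against oocytes were lower at 0 h, as were 88 of 148 with onset at 16 h, 192 of 321 from 18 h to 24 h and 218 of 909 at 36 h. Early onsets can thus be a return from a low level at 0 h, although both comparisons share the 0 h libraries. Without 10 h replicate 5 the total was 6460 and the count by 16 h 516 (7.99%). The cap-binding gene Eif4e rose at 6 h, from 190.5 CPM at 0 h to 431 CPM, and reached 799 CPM at 36 h. Cops2 (78.6 to 296 CPM), Cdc45 (42.4 to 139.6 CPM) and Eif2s1 (40.1 to 109.98 CPM) also rose at 6 h, Stip1 at 8 h (23.2 to 58.4 CPM) and the translation-associated Btf3 at 12 h (99.6 to 294 CPM). Pou5f1, the gene of the pluripotency factor OCT4, rose at 14 h from 12.1 to 35.5 CPM. At 16 h rose the nuclear-receptor coactivator Pnrc1 (40.04 to 233 CPM), the arginase gene Arg2 (15.1 to 138.1 CPM) and Oser1 (59.7 to 340.3 CPM). Timed later were Rap1b (18 h, 217 to 564 CPM) and Cox5b (20 h, 27.4 to 93.5 CPM). So were the thioredoxin Txn2 (22 h, 72.9 to 179 CPM) and the peroxiredoxin Prdx2 (36 h, 633 to 2512 CPM). Timed at 24 h, mt-Cytb (2081 to 8629 CPM) was already higher at 12 h in the pairwise test.

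**Figure D4:**
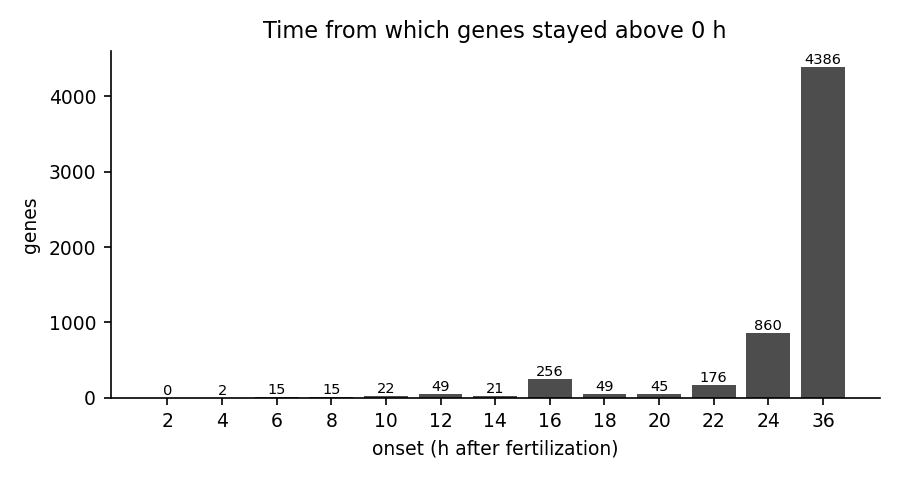
Number of genes (y axis) by assigned hour of onset after fertilization (x axis) among the 5896 genes higher at 36 h than at 0 h, with counts above bars. Counts are 256 at 16 h, 860 at 24 h and 4386 at 36 h.

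Repeat families took a median of 6.31% of all counts over the libraries, from 1.20% to 26.0%. Their share averaged 20.5 ± 2.49% (SD, n = 8) at 36 h and 12.7 ± 5.39% (SD, n = 6) at 24 h, a difference of 7.87 points (exact two-sided permutation p = 0.000666, adjusted p = 0.005 over 15 comparisons). No 36 h title has the suffix b, and among titles without it the difference was 4.47 points (exact permutation p = 0.00404), since 24 h embryos averaged 16.1% without the suffix (n = 4) and 5.86% with it (n = 2). It was lower in morulae by 11.1 points (exact permutation p = 0.000155, the smallest this design allows, adjusted p = 0.00233). It was 3.87 points higher at 16 h than at 14 h (exact permutation p = 0.0202, adjusted p = 0.0758). Families were called higher and lower in 47 and 52 of 385 tested at 0 h against oocytes, 72 and 18 of 348 at 12 h against 0 h, 186 and 6 of 521 at 24 h against 12 h, 368 and 22 of 596 at 36 h against 24 h, and 22 and 465 of 519 in morulae against 36 h. At 24 h against 12 h 36.9% of the families tested were called, and 19.5%, 21.9%, 19.8% and 13.2% without 12 h replicates 1, 3, 4 and 5 and 22.7% without 24 h replicate 1, each more than 1.5-fold fewer families.

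The MERVL internal sequence, MERVL-int, averaged 1006 ± 1501 CPM at 24 h and 8766 ± 2884 CPM at 36 h (log2 change 3.201, adjusted p = 0.0229), and 45.4 to 206 CPM in 6 morulae and 405 CPM in morula replicate 4 (log2 change -6.13). Its long terminal repeat MT2_Mm rose by 3.04 at 36 h (adjusted p = 0.00921) and changed by -3.93 in morulae, and ORR1A0 by 3.72 and -3.22. The oocyte-expressed MTA_Mm-int averaged 9262 CPM in oocytes, 4648 CPM at 0 h, 11244 CPM at 12 h, 40205 CPM at 16 h, 73203 CPM at 24 h and 55029 CPM at 36 h, and stood at 305 to 639 CPM in 6 morulae and 10911 CPM in morula replicate 4. It rose from 14 h to 16 h (log2 change 1.18, adjusted p = 0.0467) and from 12 h to 24 h (2.72, adjusted p = 0.00149), and did not pass the test from 24 h to 36 h (-0.31, adjusted p = 0.452). The 24 h mean joins separate levels, 87104 to 106240 CPM in the 4 embryos without suffix b, above all 36 h embryos (39757 to 79802 CPM), and 20891 and 22795 CPM in the 2 with it. The short interspersed B2_Mm1a rose from 5372 to 24844 CPM between 24 h and 36 h (log2 change 2.32) and B1_Mm from 195 to 816 CPM (2.15). The LINE-1 family L1Md_T changed by 2.30 at 0 h against oocytes, -1.74 at 12 h and 0.98 at 24 h, and the endogenous retrovirus IAPEz-int by 1.55, -1.91 and 1.73.

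**Figure D5:**
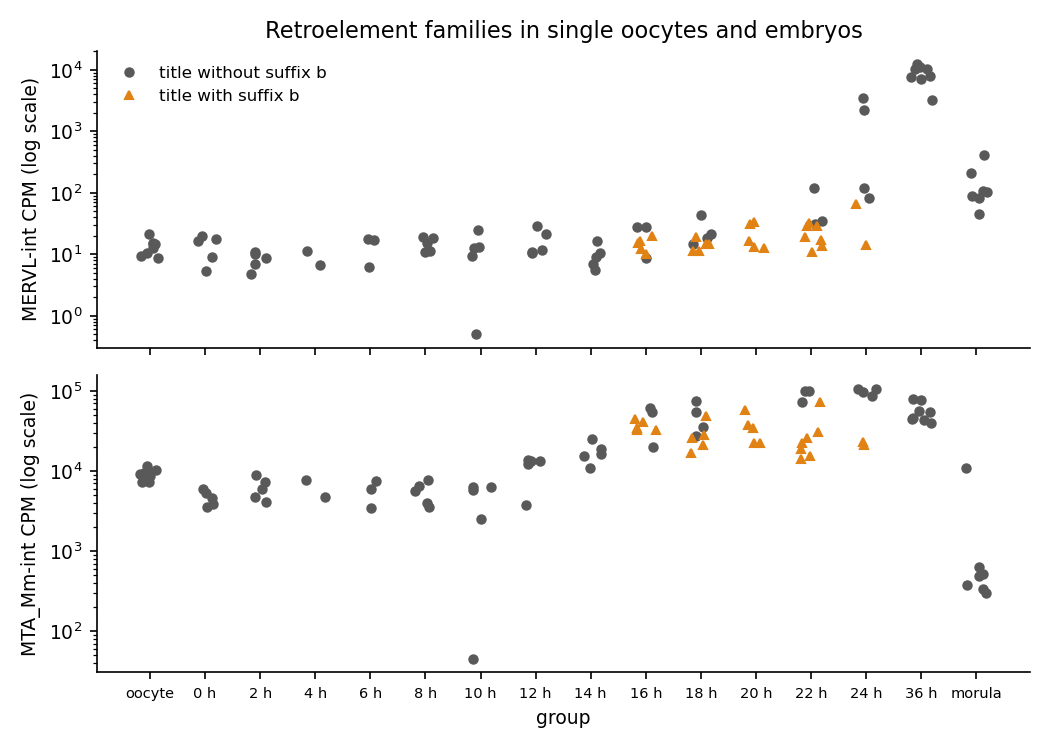
CPM of MERVL-int and MTA_Mm-int (y axes, log scale) in each library by group (x axes), with grey circles for titles without the suffix b and orange triangles for titles with it. MERVL-int reaches 3490 and 2265 CPM in 24 h replicates 1 and 4 and lies between 14.4 and 119.6 CPM in the other 24 h embryos.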

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

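The tests of the mirrored changes around 0 h, those of 10 h replicate 5, those of depth and title suffix in 24 h embryos, and the splits for the onset results were chosen only after those results had been seen. The splits of the 15 other comparisons and the test of a shared course in 24 h embryos were written down before their results were known.

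Genes that were higher at 0 h than in oocytes were mostly lower at 12 h, and the reverse, so that 0 h embryos looked less oocyte-like than 12 h embryos did. Noise of the shared 0 h libraries could produce such a mirror, but with different 0 h libraries in each comparison 1314 to 1641 genes still moved in opposite directions, against 374 to 479 for independent lists. The correlation of -0.861 that remained after trends over GC content and transcript length were removed does not by itself test them, since shared 0 h libraries alone gave -0.569 to -0.552. A monotone trend as the whole cause is argued against by the rank correlations of the change at 0 h with GC content (0.0280) and length (-0.0187). The change at 12 h had rank correlations of -0.271 with GC content and 0.0213 with length. A trend over GC content may thus hold part of that change. Similarity to the oocytes rose with the hour from 2 h to 14 h over 29 embryos (rho = 0.7096, permutation p = 3e-05). The r was 0.734 (p = 2e-05), and 0.732 without the 2 farthest embryos. With 10 h replicate 5 included r was 0.0428 and rho 0.656. Other changes can raise similarity, so oocyte batch or 0 h libraries standing apart stay open. The mirrored genes, Khdc3 and Idua among them, may owe part of the mirror to shortening and lengthening of poly(A) tails on stored messages. Poly(A)-primed libraries cannot separate tail length from abundance, and this was not tested.

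Replicate 5 of 10 h was unlike every group of the series. RNA of cumulus or other somatic cells may account for part of it, since the cumulus and granulosa list reached 3200.8 CPM, above the 1477 CPM of the next library, with Inha at 1541.5 CPM, Tnfaip6 at 617 CPM and Ptx3 at 523 CPM, while zona transcripts stood at 20.999 CPM against a mean of 15192 CPM in the other 10 h embryos. The trophectoderm list also stood at 7253 CPM, with the epithelial keratin Krt18 at 6338 CPM against 24.99 CPM in the others, and only 7 of 20 cumulus list members reached 10 CPM, so the kind of cell is left open. A library of another stage under a wrong label is argued against by its best correlation with any group mean, 0.5094, with morulae, below the lowest own-group correlation of 0.828 among libraries of at least 100000 counts. That bound was amended after the result was seen: as first written it had no minimum count and stood at 0.444, set by the shallow morula library, which 0.5094 exceeds. Low depth is argued against by its 5250912 gene counts, and no biological explanation was tested.

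Replicates 1 and 4 of 24 h held 3490 and 2265 CPM of MERVL-int and 487 and 462 CPM of Zscan4d, against 14.4 to 119.6 CPM and 3.19 to 5.20 CPM in the other 4 embryos. Thinning to the shallowest library left the lower of the pair at 2233.4 CPM, but keeps CPM on average, so it does not test depth. Replicate 5, with 4998218 gene counts against 5293393 in replicate 4, held 14.4 CPM. The title suffix b is left open: replicates 1 and 4 lacked it, as did an embryo with 82.6 CPM. Different points of 1 course to 36 h stay open. Outside the 2-cell list 0 of the other 4 embryos lay nearer to 36 h, but other genes rising by 36 h remain. Replicates 1 to 6 had gone 62.8%, 26.3%, 28.9%, 46.5%, 9.08% and 15.6% of the way from 12 h.

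Random splits of the same libraries into groups of the same sizes bear on whether each count of genes could arise from grouping alone. In 100 splits, the real one included, only the real one called as many genes for 0 h with oocytes (4371, next 838), 12 h with 0 h (3206, next 5), 24 h with 12 h (2397, next 2277), 36 h with 24 h (6607, next 3281), morulae with 36 h (8045, next 161), 2 h with 0 h (726, next 19), 16 h with 14 h (1348, next 258) and 20 h with 18 h (1, next 0), that is 1 split each. In the 24 h with 12 h comparison the split with 2277 genes put 24 h replicates 5 and 6, both with suffix b, with 12 h embryos. For 24 h with 22 h 4 of 100 splits called 36 genes or more, up to 1271, and for the onset results 1 of 25 splits gave as many genes (next 3 for both). Where 0 genes were called every split must call as many, so the splits leave chance untested there: 56 of 56 for 8 h with 6 h (up to 82) and 100 of 100 for 10 h with 8 h (up to 0), 12 h with 10 h (up to 0), 14 h with 12 h (up to 43), 18 h with 16 h (up to 81) and 22 h with 20 h (up to 875). Groups of 2 were too small for splits in the 4 h steps.

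A test for a single library far from the rest of its group was made 140 times and found 22 values in 16 libraries, where chance finds about 1 in 20 groups. Gene counts were 1534870 in 24 h replicate 6 (others 4070798 to 6795311) and 10378 in morula replicate 4 (1130566 to 4202541). Median correlation with the own group was 0.159 in 10 h replicate 5 (others 0.909 to 0.938), 0.431 in morula replicate 4 (0.920 to 0.933), 0.909 in 2 h replicate 2 (0.953 to 0.959), 0.857 in 18 h replicate 3 (0.909 to 0.948) and 0.853 in 22 h replicate 1 (0.901 to 0.939). The share of repeat families was 1.20% in 10 h replicate 5 (Wilson interval 1.19% to 1.21%; others 3.16% to 3.84%), 7.28% in 14 h replicate 2 (7.22% to 7.33%; others 4.32% to 5.01%) and 26.0% in 36 h replicate 3 (25.98% to 26.09%; others 17.5% to 21.4%). The mitochondrial share was 0.731% in 14 h replicate 4 (0.719% to 0.744%; others 1.03% to 1.11%).

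MERVL-int stood at 43.8 CPM in 18 h replicate 2 (others 11.2 to 21.02), 118.97 CPM in 22 h replicate 2 (10.99 to 35.3) and 3264 CPM in 36 h replicate 2 (7114 to 12338). MTA_Mm-int stood at 45.4 CPM in 10 h replicate 5 (2491 to 6336), 3762 CPM in 12 h replicate 4 (12187 to 13576) and 10911 CPM in morula replicate 4 (305 to 639). The 2-cell list summed to 66.6 CPM in 10 h replicate 5 (8075 to 10783). It holds stored RNA, 5145 to 6440 CPM in oocytes. It was 1438 CPM in morula replicate 4 (195 to 295). The cumulus list was 272 CPM in 16 h replicate 6 (58.1 to 118.8). Y-linked genes had 3.29 CPM in oocyte replicate 6 (2 counts, under the floor) and 120.2 CPM in 36 h replicate 1 (0.959 to 4.73). Repeat families, outside gene comparisons, had 6.31% of all counts (median).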

How the results depend on the processing

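The fits without 10 h replicate 5 and the estimated correlation without morula replicate 4 were chosen only after results had been seen. Of 31 counts of genes or lists, 8 stayed within 1.5-fold of their value under every alternative. DESeq2 size factors moved none of the 24 counts they were run for past that, and library size alone kept all main counts (4336, 3245, 2432, 6404 and 8006). Of 130 list results 76 kept their side of the threshold throughout, 35 lost a call, 19 gained one and 0 changed direction. Of 564 named-gene results 437 kept their call, 1 gained one and all others lost it under at least 1 alternative. Bub1b at 36 h against 24 h changed direction, with log2 changes of 0.15 (adjusted p = 0.673) with the replicate block and 0.080 (adjusted p = 0.902) without suffix b. Depth limits rare transcripts most in morula replicate 4. Where no cause is stated below, the cause was not tested.

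One fit of all 96 libraries called 1601 genes for 0 h with oocytes and 13219 for morulae with 36 h. A 2-fold limit left 2110 and 2124 genes for 0 h with oocytes and 12 h with 0 h, because fewer genes can pass. The fit of 81 libraries called 1620 genes for 12 h with 0 h, 1 for 2 h with 0 h, 0 for 4 h with 2 h, 566 for 10 h with 8 h, 973 for 12 h with 10 h, 273 for 16 h with 14 h, 0 for 20 h with 18 h and 966 for 24 h with 22 h. Without 10 h replicate 5 that fit called 3621 for 24 h with 12 h, 17 for 2 h with 0 h, 8 for 4 h with 2 h, 1 each for 8 h with 6 h and 12 h with 10 h, 11 for 14 h with 12 h, 4 for 20 h with 18 h and 1525 for 24 h with 22 h.

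DESeq2's test called 495 genes for 4 h with 2 h, 1 for 6 h with 4 h, 18 for 8 h with 6 h, 1 for 12 h with 10 h, 493 for 14 h with 12 h, 2051 for 16 h with 14 h, 88 for 18 h with 16 h, 13 for 20 h with 18 h, 8 for 22 h with 20 h and 278 for 24 h with 22 h. Without a filter on low counts 16826 genes were called for morulae with 36 h, 324 for 4 h with 2 h, 13 for 6 h with 4 h, 148 for 8 h with 6 h, 84 for 14 h with 12 h, 1 for 22 h with 20 h and 291 for 24 h with 22 h, and 8 lists each for 0 h with oocytes and 24 h with 12 h (from 5 and 3). Without suffix b there were 4068 for 24 h with 12 h, 624 for 16 h with 14 h and 0 for 24 h with 22 h, and with suffix b only 67 for 22 h with 20 h. With 4 h and 6 h as 1 group there were 1529 against 2 h and 1 for 8 h. A 4-fold limit left 190 genes with onset by 16 h. An estimated correlation left 0 list calls in each main comparison, from 5, 6, 3, 9 and 12, and 2 for morulae without replicate 4.

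The title number as a replicate block gave 3724, 3031, 3266, 5645 and 7504 genes and 5, 6, 3, 9 and 12 lists in the main comparisons. In the steps it gave 793 (2 h), 39 (8 h), 0 (10 h, 12 h, 14 h and 20 h), 69 (16 h), 72 (18 h), 8 (22 h) and 0 (24 h). In no comparison with at least 3 shared numbers did every same-numbered pair correlate over 0.1, so the numbers were not taken as pairs. For 6 h with 4 h no paired analysis was possible because these hours share no number, and the block fit of 4 h with 2 h, with 1 residual degree of freedom, was not run. The onset fit was not run with a block.

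With single libraries left out, genes called ranged from 3982 to 4332 (0 h with oocytes), 2680 to 3416 (12 h with 0 h), 1609 to 3231 (24 h with 12 h), 5963 to 6974 (36 h with 24 h) and 7178 to 8875 (morulae), and in the steps from 352 to 996 (2 h), 1 to 1.1e+02 (4 h, at times a single library), 0 to 4 (6 h, likewise), 0 to 4 (8 h), 0 to 307 (14 h), 503 to 1859 (16 h), 0 to 39 (18 h), 0 to 1 (20 h), 0 to 1 (22 h) and 0 to 305 (24 h), with 0 throughout for 10 h and 12 h. Without single 0 h libraries, or without 10 h replicate 5, genes higher at 36 h ranged from 5341 to 6460 and onsets by 16 h from 269 to 516. List calls ranged from 3 to 6, 5 to 8, 0 to 6, 9 to 11 and 10 to 12. Repeat families called ranged from 69 to 269 for 24 h with 12 h, from 359 to 410 for 36 h with 24 h and from 453 to 501 for morulae, and stayed within 1.5-fold of their count in the other main comparisons.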

Other observations

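Single splicing, proteasome and chromatin genes changed between stages, although the splicing and proteasome lists were not called before morulae. Lsm6, a component of U6 snRNA particles, rose from 13.4 CPM in oocytes to 119.5 CPM at 0 h, fell to 20.2 CPM at 12 h and rose to 59.9 CPM at 24 h. The proteasome gene Psma5 went from 9.12 to 122.7 and then 16.0 CPM. The chromatin assembly gene Chaf1a fell from 153 to 29.0 CPM between 0 h and 12 h. At 36 h the histone deacetylase gene Hdac1 rose from 8.32 to 66.5 CPM and the demethylase gene Kdm4c from 0.477 to 23.2 CPM, while the Polycomb methyltransferase gene Ezh2 fell from 477 to 90.97 CPM and the demethylase gene Kdm1a from 56.5 to 10.3 CPM. The cyclin E gene Ccne1 rose from 19.8 to 171 CPM and the cyclin-dependent kinase inhibitor Cdkn1a from 10.3 to 97.5 CPM.

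Single genes of junctions and signalling differed between 36 h and morulae. The claudin gene Cldn7 rose from 11.3 to 101.1 CPM in morulae without replicate 4, and Cldn6 fell from 28.9 to 1.90 CPM. Id2, a dominant-negative regulator of transcription, fell from 130.2 to 1.57 CPM, and the chaperone gene Hsp90aa1 rose from 157 to 1465 CPM. Of genes tested in both, 1136 were higher at 36 h than at 24 h and higher again in morulae, where independent lists would share 864, and 1320 were higher at 36 h and then lower, where independent lists would share 1579. Of genes higher at 12 h than at 0 h, 348 were lower at 24 h than at 12 h, where independent lists would share 175. Both pairs of comparisons share a group, which alone raises opposite calls.

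The share of repeat families differed by title suffix within hours. At 24 h it averaged 16.1 ± 1.48% (SD, n = 4) without the suffix b and 5.86 ± 0.602% (SD, n = 2) with it, and at 22 h 14.1 ± 2.11% (n = 3) and 8.88 ± 3.12% (n = 7). No test was made of this difference. Y-linked counts reached at most 12 at 16 h, 487 at 36 h and 429 in morulae.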
